A study of Caenorhabditis elegans with 2 samples.

How the data were processed

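ChIP-seq against eGFP-tagged UNC-39 was done by the authors on 2 biological replicates of L2 larvae, and the peak lists they deposited were the starting point here. Per the file listings that come with the samples, the authors called peaks on each replicate's alignments and on both replicates' alignments together, each with a control alignment. The thresholded list was made by the authors from the pooled and the per-replicate lists with the irreproducible discovery rate, per the same listings. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The control library was not analysed here. Each list is in the narrowPeak format, and the signal in its seventh column is the authors' enrichment value per peak, never negative and not comparable between lists. The significance score in the ninth column, as deposited, is below 0 for 28734 of the 30000 pooled ce11 peaks, so it was read only as a score and entered no test. Within each list all peaks have 1 width, and the summit is at the centre. The pooled ce11 list holds 30000 regions, the list of replicate 1 holds 30000 and that of replicate 2 holds 24978.

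No read counts were used, so the depth per replicate is unknown, and a difference in depth could move how many peaks a replicate's list holds and how its signals rank. Intervals on shares are exact binomial (Clopper-Pearson) intervals at 95%, and limits for counts of 0 are 3 counts of the total; both cover counting error over peaks or genes only. Peaks and genes are not independent replicates, so p-values describe these lists and not the spread between animals. There is 1 group, so no test between groups was possible.

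Peaks were ranked by pooled signal within each list. Background peaks are those of the pooled list with a summit more than 500 bp from every thresholded summit, 29827 in number; next-ranked background peaks are the 1400 of these with the highest signal, 10 for each thresholded peak. Gene positions came from Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence from the matching genome; no pooled peak ran past the end of its chromosome. No reference of ce10 was used, so that list is described by counts and signals only. A gene was assigned to a peak when a 5' end of a protein-coding transcript lay within 1000 bp of the summit. Promoters ran from 500 bp upstream to 100 bp downstream of a 5' end, and summits within 200 bp of tRNA, snRNA, snoRNA or rRNA genes were counted together and by class. A summit was matched between lists when another lay within 100 bp.

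Shares in thresholded and background peaks were compared with Fisher's exact test, two-sided, with exact conditional intervals of the odds ratio, and p-values were adjusted by Benjamini and Hochberg within a family: 7 tests of promoter, X and small RNA gene shares, 12 sequence patterns, 2080 hexamers counted together with their reverse complements, and 17 gene lists. Patterns and words were searched on both strands of the 200 bp around the summit. The matched background took 10 peaks per thresholded peak with the same promoter overlap and the same bin of GC content (5 percentage points wide), 30 short of the wanted number. Gene lists were compared over the 10680 protein-coding genes with a pooled summit within 1000 bp, and also by 10000 redraws of 140 pooled peaks. The lists were SIX-family and mesoderm regulators, muscle structure, coelomocyte, neuron fate transcription factors, genes of most neurons (synaptic, neuropeptide and other), migration and guidance, cuticle collagens, intestine, ribosomal proteins, translation and growth, germline, heterochronic genes, homeobox genes named ceh, nuclear hormone receptors, heat shock and stress, histones, and pharyngeal and glial genes. Correlations across peaks used Spearman's rho with 100000 permutations.

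The grouping, tests, alternatives, gene lists, sequence patterns and the rule for named genes were fixed before the data were examined. The rule names the 25 thresholded ce11 peaks of highest signal by protein-coding 5' ends within 1000 bp (the nearest, and the nearest on the other strand), otherwise by the nearest gene of any kind, plus every member of a gene list with a thresholded summit within 1000 bp, unc-39 and unc-119. Genes holding a summit, small RNA genes and the genes around unc-39 were named after their values were seen. The MEX word and the tests within X or autosomes were added after the peak positions were seen. Alternatives changed distances, windows, the background, the assembly and the threshold, and took each replicate's own highest 140 peaks against the rest of its list, which leaves the other replicate out.

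The tests were checked on simulated data drawn from the pooled ce11 list. With 140 random peaks, the X share had p below 0.05 in 6 of 100 draws, the promoter share in 3, and 1 or more of the 17 gene lists passed in 3; with X peaks favoured 2.5-fold the X share passed in 100 of 100, and with 8 peaks at ribosomal protein genes added that list passed in 100 of 100. These planted effects were close in size to the observed ones (X odds ratio 2.37 and 8 ribosomal protein genes reached), so smaller effects were not checked. With random peaks, 0 of 2080 hexamers passed in any of 20 draws. All 4 parts of a word planted in 20% of peaks passed in each of 20 draws, with at most 2 other words. The random peaks had the base composition of the pooled list. Thresholded peaks have a higher GC content, so the check does not cover calls that arise from it. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.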

Results

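Binding of UNC-39, a homeodomain transcription factor of the SIX4/5 family with roles in mesoderm and neuron development, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L2 larvae of Caenorhabditis elegans. The strain, OP186, carries an inserted unc-39 construct tagged with eGFP (wgIs186) in a background with the unc-119 allele ed3, and the larvae were of mixed sex. There were 2 biological replicates, each from its own biosample, and they form the only group, so the comparisons run between sets of peaks and not between conditions. Peak lists were used on the ce11 assembly, with a second version on ce10. The lists hold no read counts, so the depth of each replicate is unknown. Signal per peak is the authors' own value and was used only to rank or describe peaks within a list.

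The thresholded list held 140 peaks on ce11, each 364 bp wide, with signals from 45.9 to 139 and a median of 55.2. These were exactly the 140 peaks of highest signal in the authors' pooled list of 30000 peaks and background regions, where the median signal was 17. The highest peak (chromosome III, 10759069 to 10759432, signal 139) lay between genes, 56 bp upstream of the 5' end of tasp-1, a gene for a taspase-like protease, and 729 bp upstream of K01G5.10 on the other strand. The second (X, 13700729 to 13701092, signal 136) had no protein-coding 5' end within 1000 bp, and the third (III, 3867391 to 3867754, signal 122.1) lay 281 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. The fourth (X, 11094036 to 11094399, signal 114) was intergenic, with a tRNA gene as the nearest 5' end, and the fifth (X, 6296378 to 6296741, signal 105) was in an intron of mom-1, a Wnt secretion gene.

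The peak of rank 6 (I, 4172166 to 4172529, signal 93.5) lay 33 bp from sls-2.4, an SL2 spliced-leader RNA gene, and 759 bp upstream of egg-5. The peak at iff-2, which encodes a homologue of translation factor eIF-5A, had a signal of 75.3, with its summit 37 bp upstream of the 5' end. A peak with signal 82.6 lay 806 bp upstream of spc-1, the alpha-spectrin gene. A peak with signal 73.1 lay 215 bp upstream of a 5' end of rgs-6, a regulator of G protein signalling, and one with signal 68.8 lay 237 bp upstream of a 5' end of daf-19, an RFX transcription factor of ciliated neurons. Other protein-coding genes with a 5' end within 1000 bp of these summits were F46H5.2, T24B8.3, Y39B6A.43, B0348.10 and F54C9.14, and the peak of rank 10 (signal 89) was in a coding exon of pks-1, a polyketide synthase gene. The B0348.10 peak ranked 29 in replicate 2's own list and 1817 in that of replicate 1.

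The X chromosome held 50 of the 140 thresholded peaks, 35.7% (95% exact binomial interval 27.8 to 44.2), against 19% of the 29827 background peaks, which are pooled peaks more than 500 bp from any thresholded summit. Of the 25 highest peaks 14 were on X, and of the 10 highest 7 were. Chromosome II held 9.29% of thresholded and 15.8% of background peaks, chromosome III 10% and 14%, and chromosome I 14.3% and 14.8%. The X share was higher than in background peaks by Fisher's exact test, two-sided (odds ratio 2.37, 95% interval 1.64 to 3.39, p = 3.87e-06, adjusted p = 2.71e-05 over 7 tests). It was 36.4% among the 140 highest peaks of replicate 1's own list and 35% among those of replicate 2. The p-value runs over peaks, which are not independent replicates.

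**Figure D1:**
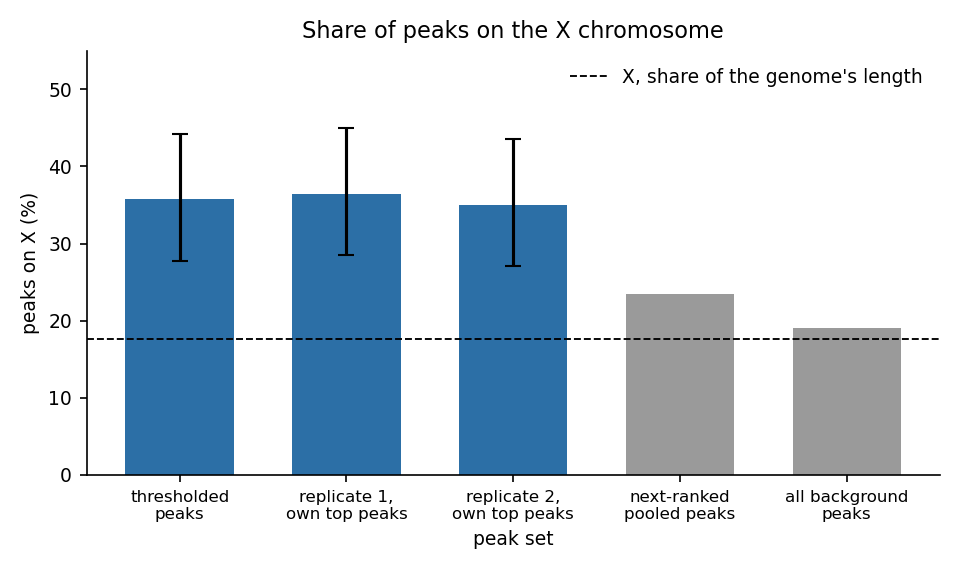
Share of peaks on the X chromosome (%, vertical axis) in 5 peak sets, with 95% exact binomial intervals for the sets of 140 peaks. The thresholded peaks (35.7%) and each replicate's own highest 140 peaks (36.4% and 35%) lie above the 1400 next-ranked pooled peaks (23.5%), all background peaks (19%) and the share of X in the length of the genome (17.7%, dashed line).

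Sequence around the X peaks contained pieces of a 12-base word, TCGCGCAGGGAG, known as the MEX motif of the sites that recruit the dosage compensation complex to X. On X alone, the hexamers AGGGAG, CCCTGC, CTGCGC and CGCGCA, all parts of that word or of its reverse complement, had the smallest p-values of the 2080 tested, with AGGGAG in 38% of thresholded and 5.35% of background X peaks (Fisher's exact test, adjusted p = 1.40e-08). All 4 were also more frequent in thresholded than in background autosomal peaks, at 17.8% and 5.25%, 8.89% and 2.53%, 11.1% and 2.80%, and 13.3% and 3.44%. The MEX word, chosen after the peak positions were seen, was present with at most 2 mismatches in 10 of 50 thresholded X peaks (20%) and in 0.477% of background X peaks (odds ratio 51.9, 95% interval 21 to 120, p = 2.96e-13, Fisher's exact test). The 10 included the intergenic peak of rank 4, the mom-1 intron peak and the pks-1 exon peak. On autosomes 0 of 90 thresholded peaks held the word, which allows a share of up to 3.33%, against 0.422% of background peaks. At up to 3 mismatches the word was not confined to X. It was in 44% of thresholded and 5.58% of background X peaks. On autosomes it was in 17 of 90 thresholded (18.9%) and 5.35% of background peaks (odds ratio 4.12, 95% interval 2.27 to 7.08, Fisher's exact p = 5.58e-06). The comparisons of the word and of hexamers within X or autosomes used no background matched on GC content. Median GC content was 47.8% in thresholded and 38% in background X peaks, and 50.8% and 38.5% on autosomes. A word of the same letters in random order, at up to 2 mismatches, was in 0 of 50 thresholded X peaks (up to 6%). It was in 0.265% of background X peaks. Across the genome, 11 of 32 X sites with at most 1 mismatch lay within 100 bp of a thresholded summit. On autosomes 0 of 37 such sites did (Fisher's exact p = 7.07e-05). With at most 2 mismatches the counts were 19 of 284 X sites (6.69%) and 0 of 1362 autosomal sites. Several sites can share a peak.

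**Figure D2:**
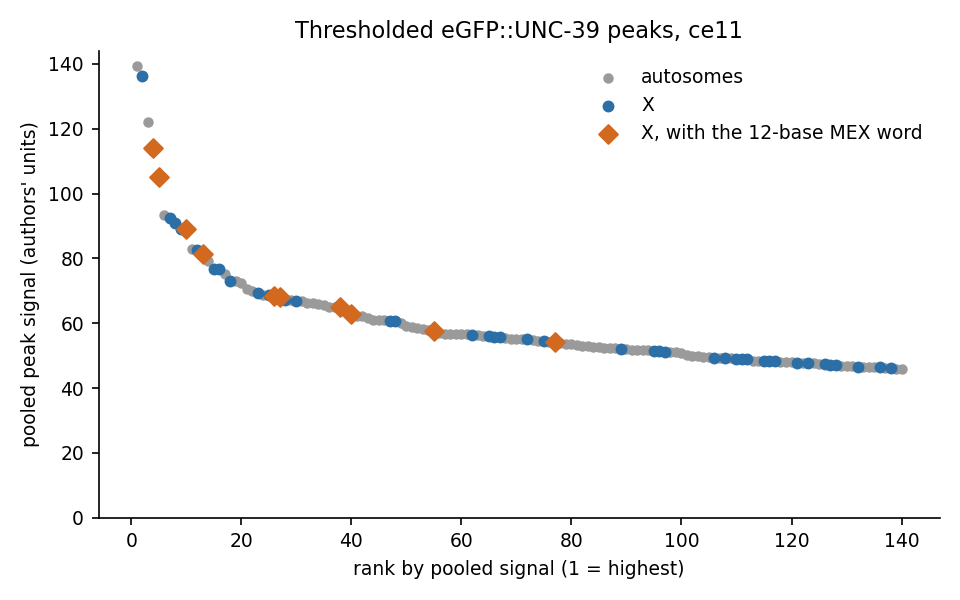
Pooled signal (authors' units, vertical axis) of the 140 thresholded peaks against their rank (horizontal axis), with autosomal peaks in grey, X peaks in blue and the 10 X peaks holding the MEX word as diamonds. X peaks take 14 of the 25 highest ranks, and the peaks with the MEX word run from rank 4 to rank 77.

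Thresholded peaks lay mostly outside coding sequence. Summits were outside protein-coding genes for 67.9% of thresholded and 32.4% of background peaks, a class that includes summits inside noncoding RNA genes. They were in introns for 21.4% and 29.6%, in untranslated exons for 5% and 4.90%, and in coding exons for 5.71% and 33.1%. Promoters of protein-coding genes, from 500 bp upstream to 100 bp downstream of a 5' end, held 43 of 140 thresholded summits (30.7%, 95% exact binomial interval 23.2 to 39.1) and 15.7% of background summits (odds ratio 2.38, 95% interval 1.62 to 3.45, Fisher's exact p = 1.11e-05, adjusted p = 3.90e-05). On autosomes the shares were 36.7% and 16% (odds ratio 3.04), and on X 20% and 14.3% (odds ratio 1.49, Fisher's exact p = 0.308); this split was chosen after the data were seen, and the difference between X and autosomes was not tested. Among replicate 1's own highest 140 peaks the promoter share was 20.7% and not past the threshold (odds ratio 1.47, exact p = 0.0754).

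Small structural RNA genes (tRNA, snRNA, snoRNA or rRNA) lay within 200 bp of 9 thresholded summits (6.43%) and of 1.15% of background summits (odds ratio 5.90, 95% interval 2.62 to 11.7, Fisher's exact p = 4.37e-05, adjusted p = 1.02e-04). Among them 3 were at the SL2 RNA genes sls-2.4, sls-2.2 and sls-2.1, with signals of 93.5, 66.2 and 58.6, for an snRNA odds ratio of 26.1 (exact adjusted p = 5.25e-04). There were 4 at tRNA genes (odds ratio 4.42, exact adjusted p = 0.0208) and 2 at the snoRNA genes C51F7.4 and M7.15 (adjusted p = 0.130). No thresholded summit lay near an rRNA gene, where only 1 background summit did. Set against only the 1400 next-ranked peaks, of which 4.29% lay near such a gene, the excess was not past the threshold (odds ratio 1.53, exact p = 0.279). Whether these genes would give peaks with any antibody was not tested, because no other factor or control library was analysed here. The sls-2.2 peak had no summit within 100 bp in replicate 1's list, and the sls-2.1 peak had none in that of replicate 2.

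Ribosomal protein genes stood out among the 17 gene lists. A thresholded summit lay within 1000 bp of a 5' end of 8 of the 62 ribosomal protein genes in reach of any pooled peak (12.9%), against 0.753% of other genes (odds ratio 19.5, 95% interval 7.76 to 43, Fisher's exact adjusted p = 6.15e-07). They were rpl-3 (signal 122.1), rpl-20 (66.4), rpl-27 (62.2), rpl-12 (60.1), rps-12 (57), rps-28 (56.6), rpl-15 (53) and rpl-35 (48.5). The summit lay from 9 to 455 bp upstream of the 5' end at all of these except rpl-27, where it was 759 bp downstream. Other genes had nearer 5' ends at 3 of the 8 peaks: egl-30, a G protein alpha subunit gene, at the rpl-27 peak (19 bp), ska-3 at the rps-12 peak (95 bp against 198) and Y17G9B.5 at the rpl-20 peak (177 bp against 285). In 10000 redraws of 140 pooled peaks the p was 9.999e-05, the smallest the redraws can give. With each replicate's own highest 140 peaks, 4 of 55 members were reached in replicate 1 and 6 of 62 in replicate 2 (exact adjusted p = 0.00835 and 3.63e-04). The rpl-15 peak ranked 28 in replicate 2 and 27284 in replicate 1, and the rpl-27 peak had no partner in replicate 1's list.

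Heterochronic genes, which time larval development, were reached at 2 of 12 members (16.7%), ain-1, a GW182-like factor of microRNA silencing (signal 60.6), and lin-66 (signal 56.7), with an adjusted p of 0.0357 by Fisher's exact test. This call was lost in redraws of peaks (adjusted p = 0.0980), at 500 bp (exact adjusted p = 0.422) and in replicate 1's own highest peaks (adjusted p = 0.498), and the lin-66 peak ranked 1777 in that list; it held within 2000 bp (3 of 13, exact adjusted p = 0.00151). The list of genes of most neurons was reached at 2 of 21 members, egl-21, a carboxypeptidase of neuropeptide processing (signal 55.3), and unc-76 (signal 49.7), without passing the threshold (adjusted p = 0.0722, Fisher's exact test). That list did pass within 2000 bp (5 of 31, exact adjusted p = 1.14e-04) and in replicate 2's own highest peaks (3 of 21, exact adjusted p = 0.00766). Migration and guidance genes were reached at unc-115 and mig-38, 2 of 32 members (exact adjusted p = 0.121). Translation and growth factors had iff-2 (1 of 27, exact adjusted p = 0.568), heat shock and stress genes had hsp-3 (1 of 44, exact adjusted p = 0.742), and histone genes had his-37 (1 of 20, exact adjusted p = 0.519). Translation and growth factors passed in replicate 1's own highest peaks (3 of 26, exact adjusted p = 0.00835) and histone genes within 2000 bp (3 of 31, exact adjusted p = 0.0156).

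No thresholded peak lay within 1000 bp of a 5' end of any of the 22 SIX-family and mesoderm regulators in reach, a count that allows a share of up to 13.6%. The count was also 0 for 36 muscle structure genes (up to 8.33%), 10 coelomocyte genes (up to 30%) and 34 neuron fate transcription factors (up to 8.82%). It was 0 again for 33 homeobox genes named ceh, 159 nuclear hormone receptors, 108 cuticle collagens, 34 intestine genes, 21 germline genes and 16 pharyngeal and glial genes. By Fisher's exact test none of these 10 lists differed from other genes (unadjusted p from 0.644 to 1). With 88 genes reached in all, at 75 of the 140 peaks, redraws of peaks gave a mean of 1.04 genes or fewer for each of these lists, too few for a lower share to be detected.

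None of the 3 SIX-family words tested passed the threshold in either direction. The MEF3 site TCAGGTTTC with at most 1 mismatch was within the central 200 bp of 3 of 140 thresholded peaks (2.14%) and of 6.29% of background peaks (odds ratio 0.326, 95% interval 0.0664 to 0.976, Fisher's exact adjusted p = 0.0877 over 12 patterns). Its reversed form CTTTGGACT, a control of equal base content, was at 0.714% and 3.71% (exact adjusted p = 0.102). The SIX-family core TGATAC was at 5% and 6.71% (exact adjusted p = 0.546), and the fly Six4 core TGACAC at 11.4% and 8.15% (odds ratio 1.45, 95% interval 0.805 to 2.46, adjusted p = 0.194), an interval that leaves an excess open. The GA repeat GAGAGAGA was the most enriched pattern, at 19.3% and 2.38% (odds ratio 9.81, 95% interval 6.15 to 15.2, exact adjusted p = 1.05e-15). It stayed at 19.3% against 4.82% beside background matched on GC content and promoter overlap (odds ratio 4.71, exact adjusted p = 1.55e-07), and against 6.93% of the next-ranked peaks (odds ratio 3.21, exact adjusted p = 6.64e-05).

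The E-box CAGCTG was at 10% and 4.87% (odds ratio 2.17, exact adjusted p = 0.0294), and this call was lost with the matched background (odds ratio 1.15, adjusted p = 0.834), against next-ranked peaks (1.83) and in the highest peaks of replicate 1 (1.53) and replicate 2 (1.21). In a split chosen after the data were seen, CAGCTG was in 9 of 50 thresholded X peaks (18%) against 4.06% of background (odds ratio 5.18, Fisher's exact adjusted p = 0.00112). On autosomes it was in 5.56% and 5.07%. The split had no matched background, and median GC content was 47.8% in thresholded and 38% in background X peaks. The other E-box, CACGTG, the HOX-PBX site and the RNA polymerase III B box did not pass (exact adjusted p = 0.670, 0.0643 and 0.110). The B box did pass in replicate 2's own highest peaks (6 of 140, odds ratio 3.96, exact adjusted p = 0.0160), and the HOX-PBX site had a lower share within 400 bp (exact adjusted p = 0.00701). Lower shares than in background were found for the GATA factor site TGATAA (5.71% and 16.4%, exact adjusted p = 0.00127), a block of T (7.14% and 16.4%, adjusted p = 0.00736) and the ETS site CCGGAA (2.86% and 8.50%, adjusted p = 0.0330), of which CCGGAA alone passed with the matched background (adjusted p = 0.00969). Against the next-ranked peaks none of these lower shares passed (odds ratios 0.463, 0.758 and 0.479, exact adjusted p = 0.146, 0.714 and 0.343). None passed within 100 bp either, where words are fewer, but the odds ratios there were close to those in 200 bp or lower (0.313, 0.400 and 0.155 against 0.309, 0.391 and 0.317). The block of T did not pass within 400 bp (25% and 30.7%, exact adjusted p = 0.201), and CCGGAA did not pass in the 70 thresholded peaks of higher signal, where its odds ratio was the same (0.317), or in replicate 1's own highest peaks (0.397). The TGATAA share was 8.57% in replicate 1's own highest peaks (odds ratio 0.466) and 1.43% in those of replicate 2 (odds ratio 0.0736). In the split chosen after the data were seen, TGATAA and the block of T passed on autosomes only. Their odds ratios were 0.307 and 0.238 there, and 0.295 and 0.672 on X, where thresholded peaks are fewer. CCGGAA passed in neither (odds ratios 0.361 on autosomes and 0.250 on X). Median GC content was 50% in thresholded and 38.5% in background peaks. Of 2080 hexamers, 353 were more and 249 less frequent in thresholded peaks, with the smallest p-values for AGAGAG (49.3% and 11.1%), GAGAGA (50% and 13.6%), CACACA (43.6% and 10.7%) and, among the less frequent, AAAATT (13.6% and 52.4%). With the matched background, which is also smaller (1370 peaks), the numbers were 106 and 45.

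**Figure D3:**
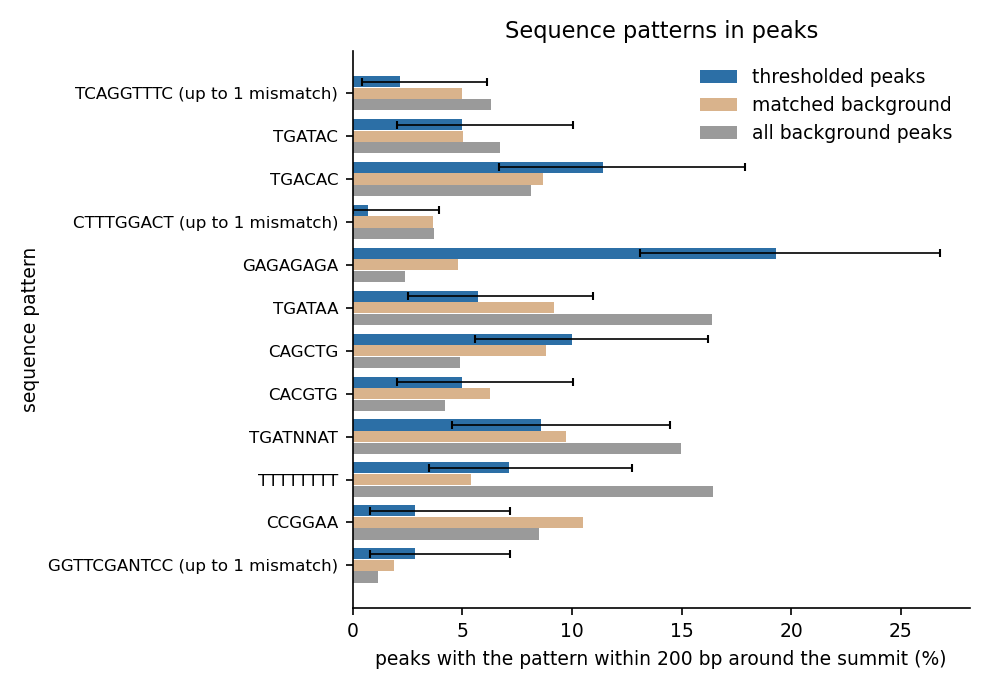
Share of peaks (%, horizontal axis) with each of 12 sequence patterns in the central 200 bp, for the 140 thresholded peaks (with 95% exact binomial intervals), 1370 background peaks matched on GC content and promoter overlap, and all 29827 background peaks. GAGAGAGA is at 19.3% in thresholded peaks and at 4.82% and 2.38% in the background sets, while the MEF3 site TCAGGTTTC is at 2.14%, 4.96% and 6.29%.

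At unc-39 itself (V, 14373074 to 14375881) there was no thresholded peak within 20 kb and there were 2 pooled peaks, with a median signal of 17.7, a level that 30.2% of protein-coding genes reached or passed in their own 20 kb surroundings. In the replicates' own lists the level was below the median of genes, reached or passed by 95.1% in replicate 1 (1 peak) and by 86.1% in replicate 2 (3 peaks). No pooled summit lay within 10 kb of the gene. The nearest thresholded peak (V, 14350981 to 14351344, signal 47.6) was 21911 bp away, in the area of cept-2 and vha-13. The pooled list had no summit between 14356439 and 14403319, a stretch of 46880 bp that holds unc-39, npr-43, Y49A3A.4, C15H11.10, C15H11.1 and C15H11.13. The 29994 intervals between neighbouring summits had a median of 2187 bp and only 5 of them were longer than this stretch, and the replicates' own lists had intervals of 47188 and 46884 bp there. At unc-119 (III, 10902641 to 10908935), the gene of the strain's marker allele, 7 pooled peaks lay within 20 kb and none was thresholded. A pooled summit lay inside unc-119 (signal 25.8). The interval between pooled summits there was 10341 bp, and 14% of protein-coding genes lie within one as long.

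**Figure D4:**
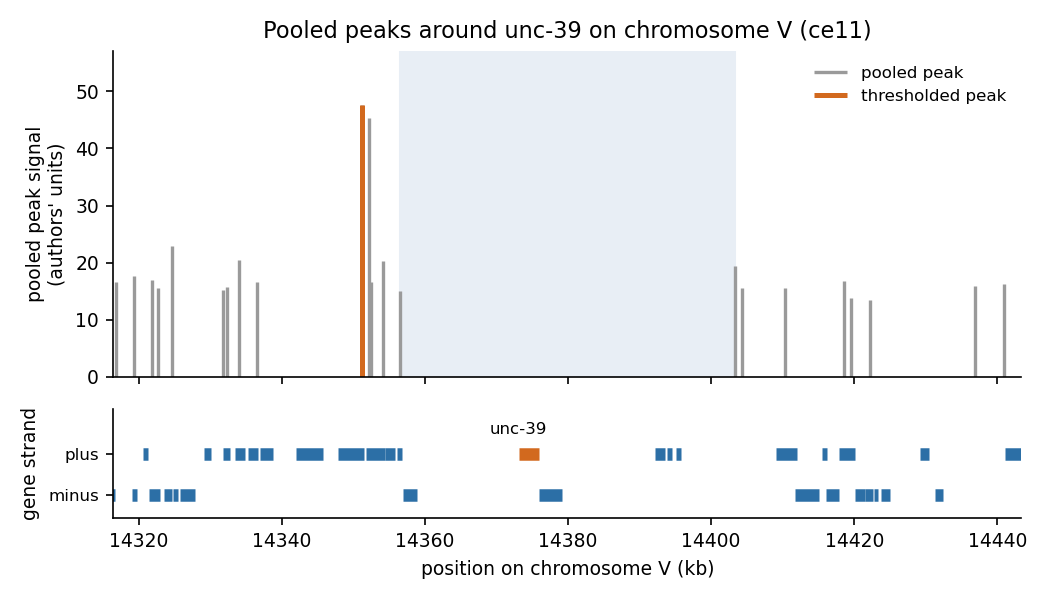
Signal of pooled peaks (authors' units, upper panel) and protein-coding genes by strand (lower panel) along chromosome V of ce11 (kb), with thresholded peaks and unc-39 in orange. The shaded stretch of 46880 bp around unc-39 contains no pooled summit.

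The highest peaks recurred in both replicates, and the order of the others differed between them. The peaks at tasp-1, at X 13700729 to 13701092 and at rpl-3 took ranks 1, 2 and 3 in replicate 1 and 3, 1 and 2 in replicate 2. Of the 140 thresholded peaks 97 (69.3%, 95% exact binomial interval 60.9 to 76.8) had a summit within 100 bp among the top 1000 of both replicates, against 38 (27.1%) of the next-ranked 140 pooled peaks and 0.161% of all background peaks. Replicate 1's top 1000 held 109 of them and replicate 2's 127. The replicates' own top 140 lists shared 38 peaks (27.1%), and their top 1000 lists 140 (14%). Since the thresholded list was made from the same replicates, these shares describe it and do not test it.

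Across the 121 thresholded peaks matched in both lists, the replicates' signals had a Spearman's rho of 0.0893 (permutation p = 0.330) and a Pearson's r of log2 signal of 0.187 (permutation p = 0.0389). Without the 2 peaks farthest from the median pooled signal rho was 0.0426, with summits matched within 50 bp 0.154 (permutation p = 0.176), and among the 62 matched of the 70 thresholded peaks of higher signal 0.245 (permutation p = 0.0561). These are correlations across peaks, which are not independent replicates, and choosing peaks by pooled signal narrows the range. Across all 5714 pooled peaks matched in both lists rho was 0.186 (permutation p = 0.001, the smallest that 1000 resamples can give).

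**Figure D5:**
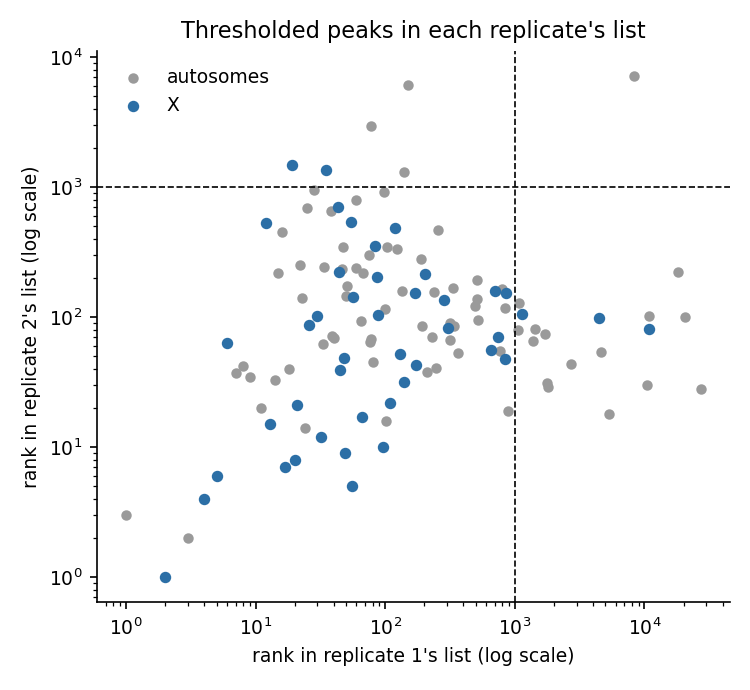
Rank of each of the 121 thresholded peaks matched in both replicates' own lists, replicate 1 on the horizontal and replicate 2 on the vertical axis (both log scales), with X peaks in blue and dashed lines at rank 1000. The 5 peaks of highest pooled signal lie at the lower left in both, and several peaks high in replicate 2 lie beyond rank 1000 in replicate 1.

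On ce10 the thresholded list held 128 peaks, 12 fewer than on ce11, of which 47 were on X (36.7%). Of the 128 pairs of equal rank in the lists of both assemblies, all but 13 had signals within 0.01 of each other. By chromosome the ce11 list had 2 more peaks on I, 2 on II, 0 on III, 1 on IV, 4 on V and 3 on X. Gene names and sequences were taken on ce11 only.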

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

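The alternatives without MEX-word or promoter peaks, those within autosomes or X alone, and the redraws of gene lists were chosen after the data were seen. The X share stayed past its threshold under all alternatives run, with odds ratios from 1.64 without peaks holding the MEX word at up to 3 mismatches to 2.93 without promoter peaks, and from 2.27 to 2.45 with 1 replicate left out. The promoter odds ratio was 1.49 on X alone and ran from 1.47 to 2.20 with 1 replicate left out, the lower value being replicate 1's list alone. That of small RNA genes fell to 1.53 against next-ranked peaks and was 5.34 to 7.61 with 1 replicate left out. The 70 peaks of higher signal had a replicate support of 84.3%, and over all 140 it was 82.9% by overlapping intervals, 50.7% with summits within 50 bp, 55% in the top 500 and 86.4% in whole lists, as the wider or narrower criteria set it. The replicates' signals correlated at 0.186 over all matched pooled peaks and at 0.187 by Pearson's r, and at 0.154 within 50 bp and 0.245 in the 70 higher peaks, neither past the threshold. Patterns more frequent than in background numbered 1 instead of 2 with windows of 100 or 400 bp, the matched background, next-ranked peaks, the 70 higher peaks or autosomes alone, and 1 or 2 with 1 replicate left out. The pattern kept in all of these was GAGAGAGA, and CAGCTG was lost in each. The odds ratio of CAGCTG was 2.17 as before in the 70 higher peaks, 2.03 in 100 bp, 1.73 in 400 bp and 1.83 against next-ranked peaks. It was 1.15 with the matched background, 1.10 on autosomes and 1.21 to 1.53 with 1 replicate left out. Without replicate 1 the second pattern was the B box. On X alone both GAGAGAGA and CAGCTG passed, against background not matched on GC content. Hexamers numbered 225 in 100 bp, 106 with the matched background, 201 in the 70 higher peaks, 124 on X alone and 226 to 310 with 1 replicate left out. Gene lists past the threshold numbered 1 within 500 bp and in redraws, 4 within 2000 bp (genes of most neurons and histones gained), and 2 to 3 with 1 replicate left out. Without replicate 1 genes of most neurons were gained, and without replicate 2 translation and growth took the place of heterochronic genes. The share of genes with a median signal as high as around unc-39 was 17.2% within 40 kb and 86.1% to 95.1% with 1 replicate left out; within 10 kb no value could be had because no pooled summit lay there. Where no reason is given, the cause was not tested. No paired analysis was possible because there is 1 group. Depth was unknown, so its effect on the replicates' lists could not be measured.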

Other observations

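The test of the stretch length around unc-39 and that of the share of ribosomal protein gene peaks with SIX-family words were chosen after their results were seen, and the tests with the MEX word and of microRNA genes after the peak positions were seen. Peaks near microRNA genes were few. Among thresholded summits 3 lay within 500 bp of a microRNA gene, at mir-54 on X (291 bp, signal 90.9), mir-2 on I (417 bp, signal 58.1) and mir-52 on IV (102 bp, signal 54.9). Within 200 bp there was 1 of 140, against 0.171% of background summits (Fisher's exact p = 0.216). These genes were named after their values were seen.

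The excess of thresholded peaks on X came without a rise in the median signal of background peaks there. This median was 1.01 times that of autosomal ones (95% bootstrap interval 0.998 to 1.02). A factor of 1.28 would be needed to give X its share of the highest peaks. The pooled list ends at a signal of 13, near its median of 17, so the median may move little with a rise. X also held 23.5% of the 1400 next-ranked peaks against 19% of all background peaks, so a rise confined to stronger peaks stays open. Recruitment sites of the dosage compensation complex may account for part of the X peaks, with an odds ratio of 51.9 for the MEX word; leaving out peaks with that word lowered the X odds ratio to 1.90 (95% interval 1.27 to 2.78), so peaks with a recognisable word do not make up the whole excess, although at up to 3 mismatches the interval came close to 1 (1.64, 1.02 to 2.57). At that setting the word is not specific to X, being enriched in autosomal peaks as well (odds ratio 4.12), so the looser removal took out peaks of both kinds. GC content was not matched in these comparisons. At up to 2 mismatches, GC content alone would also put the word in autosomal thresholded peaks, whose median GC content was higher (50.8% against 47.8% on X). It was in 0 of 90 of them and in 10 of 50 on X. The same letters in random order were in 0 of 50 X peaks (up to 6%). Both values argue against GC content alone as the source of the word's excess at that setting. At up to 3 mismatches its part is unknown. Binding through a MEF3 site was not what set X peaks apart (odds ratio 0.281, upper limit 1.65), and the upper limits for TGATAC and TGACAC on X, 2.61 and 2.69, leave those cores open. Signal from accessible or densely bound chromatin, not tested because no other factor or control library was analysed here, stays open, as does binding of UNC-39 beside the complex.

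Neighbouring members of the list sharing a peak did not make up the number of ribosomal protein genes reached (redraw p of 9.999e-05, the smallest possible). The redraws do not test which gene a peak belongs to. Nor did promoter peaks of any kind account for that number. Among promoter peaks alone, 8 of 43 thresholded and 40 of 4682 background peaks were at such genes (odds ratio 26.4, 95% interval 9.96 to 62.8, Fisher's exact p = 6.85e-09). The 8 include the rpl-27 peak, which lay in the promoter of egl-30. A MEF3 site is not what all of these peaks share, since 0 of 8 held the word in the central 200 bp (upper limit of the share 36.9%) and 1 of 8 in 400 bp (upper limit 52.7%), but the wider window leaves open whether most do, and the odds ratio against background promoter peaks (upper limit 9.47) does not decide for part of them. The bound set in advance was met by all 43 promoter peaks (upper limit 1.45), but most of these are not at ribosomal protein genes. Of the other SIX-family cores, TGATAC was in 3 of the 8 (95% interval 8.52% to 75.5%) and TGACAC in 0 of 8, in 200 bp and in 400 bp alike. These counts were not tested against background, so binding through a SIX-family site stays open. At 3 of the 8 peaks another gene's 5' end was nearer, so those peaks may belong to it, and whether transcription level alone could bring these promoters up was not tested.

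The stretch of 46880 bp without pooled summits around unc-39 was not of ordinary length, since 0.491% of protein-coding genes lie within one as long, and repeated sequence does not account for it: 4.86% of its 32-base words occur more than once in the genome, against a median of 5.77% in 1000 random stretches of that length, 56.5% of which had as large a share, while the 5 longer stretches had from 50.2% to 93.4%. A candidate explanation is that extra copies of the locus in the inserted construct raised control reads over it, so that no region there passed as a peak. The signal of the flanking peaks does not decide this. It rests on 2 pooled peaks, at a level reached by 30.2% of genes within 20 kb. In the replicates' own lists it rests on 1 and 3 peaks, at levels below the median of genes (95.1% and 86.1%). The 2 pooled peaks lie 16635 and 18902 bp from unc-39, at or beyond the edge of the stretch. A level among the highest 5% of genes was set before the test as the mark of extra copies. A level below the median of genes was to count against them. The pooled level met neither rule, and the levels in the replicates' own lists met the second. That raised control reads could instead lower the signal was not part of that rule and was not tested. The extent of the construct and the control reads were not analysed here, and if extra copies were the cause the absence of peaks at unc-39 would say nothing about binding of UNC-39 to its own gene.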
